A study of Mus musculus with 18 samples.

How the data were processed

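Total RNA was taken from Wt1-GFP bright cells sorted from the dissociated heart ventricles of Wt1GFP knock-in mouse embryos, with lysis buffer added after the sort. Per the labels' protocols, biotinylated cRNA made from 200 ng of RNA was hybridised to Illumina bead arrays. The 18 arrays fall into 6 stages, E11.5 to E16.5, of 3 arrays each, and the stage and replicate number of each array came from its title. The submitters' processing notes name GenomeStudio 2011.1, and the normalization method, the background step and the probe filter are not given in the sources used here.

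The deposited values are probe intensities on a linear scale, from 83.8 to 17358 with a median of 104. The sorted values of the 18 columns differed by at most 2.04 intensity units, so the authors' deposited intensities are quantile normalized, and their lowest value lies far above 0, which background that was not subtracted or an offset added later would each give. A second table of signals with detection p-values was not used here, since its 18 signal columns and 18 detection p columns carry running numbers that match no label. When it was first examined, each of its signal columns had a rank correlation of 1, to rounding, with exactly 1 column of the value table, which points to the array each belongs to, but arrays were assigned by column names and never by values. The design fixed before the data were examined had called for background correction of that table, so log2 of the deposited intensities took its place and a floor set from the values took the place of detection p. For arrays their number limits the precision, and signal over background limits what can be seen of dim genes. All arrays share 1 distribution, so no array can be called deeper than another.

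The background had its mode at 99.0 intensity units and an SD of 0.059 on the log2 scale, and the floor at a tail of 0.01 was 109 intensity units (6.77 on the log2 scale). Of 45281 probes 20268 lay above the floor on at least 3 arrays and were kept, and 12523 lay above it on all 18. The platform's gene table gave 1 symbol for 34885 probes, several for 18 and no listed one for 10378. Of those with 1 symbol 34807 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez number, and 0 symbols changed. That table served for names, and no coordinates are printed because the files name no build. Of the kept probes 3131 had no single symbol and were not tested as genes. A gene with several kept probes, as 4226 had, was represented by the probe with the highest mean, which left 10950 genes. Of 147 genes named in the E16.5 against E11.5 comparison 77 had other kept probes. For 50 of these an other probe differed by less than 50% of the printed change, and for 1, Masp1, an other probe went the opposite way. Where a gene was under the floor on all 3 arrays of the dim stage the text gives "at least N-fold", the mean of the bright stage against the floor, and where 1 or 2 of the 3 were above it the text says how many.

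Differences were tested with limma 3.58.1 (lmFit, contrasts and eBayes, with 12 residual degrees of freedom per gene) in R 4.3.3, on all 18 arrays with 1 mean per stage and no covariate, and adjusted by Benjamini-Hochberg. Sample tables were read with jsonlite 2.0.0. Genes with an adjusted p under 0.05 were called, and those with an absolute log2 difference of at least 1 were counted separately. The comparisons were an F test of the 6 stages, E16.5 against E11.5, the slope per day, the early window (E13.5 against E11.5), the late window (E16.5 against E14.5), the late minus the early window, and the 5 steps between neighbouring days. Log2 differences are of intensities with that level included.

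Before the data were examined 33 gene lists with 776 entries were fixed, of which 584 were measured. Those with at least 5 measured genes, 32 in number, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the lists. The lists were epicardial and mesothelial identity, epithelial junctions and polarity, epithelial-mesenchymal transition, fibroblast, smooth muscle and pericyte, endothelial and endocardial, cardiomyocyte, erythroid, leukocyte, and neural crest and Schwann markers. Further lists were S phase genes, G2/M genes, cell cycle inhibitors, the retinoic acid, BMP, TGF-beta, Wnt, FGF and Notch pathways, Hippo-YAP, PDGF, IGF and chemokine signals, basement membrane, interstitial matrix, complement and interferon response. The others were developmental timing, imprinted growth genes, glycolysis and hypoxia, oxidative phosphorylation, immediate early genes, apoptosis regulators, the cytoskeleton and sex chromosome genes.

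Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls between E16.5 and E11.5 among genes called with at least a 2-fold difference, no overlap between the arrays of the stages and all 3 arrays of the higher stage above the floor. It added up to 4 called members with the largest difference from each list, the 3 largest rises and falls of each window and step, the 4 largest differences each way between the windows, and 14 genes fixed by name. Of these 14, Wt1, Mki67 and Tnnt2 were not analysed here. Members of lists named for their window changes were chosen after their values were seen unless this rule names them.

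The scripts were tested on simulated arrays with 10950 genes. Their noise was normal and independent between genes, and only the genes counted here were changed. The real arrays hold correlated genes and arrays that stand apart, so these counts may not carry over to them. For E16.5 against E11.5 they recovered 56 of 67 genes changed by 0.5 on the log2 scale, 63 of 67 changed by 1 and 66 of 66 changed by 2, with 9 false calls. For the difference between the windows they recovered 36 of 67, 62 of 67 and 65 of 66, with 7 false calls, and for the slope per day 58 of 67, 67 of 67 and 66 of 66, with 13 false calls.

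Whether equal replicate numbers pair arrays was checked with the correlation of deviations from the stage means. Every same-number correlation was over 0.1 for E11.5 with E12.5 (lowest 0.22), E11.5 with E16.5 (0.21) and E15.5 with E16.5 (0.36) among the pairs of stages compared. Equal numbers may therefore pair these arrays. This comes from the values, the cut of 0.1 was not tested against chance, and the labels do not say what a number stands for. Alternatives tried were other background corrections, offsets, scalings, filters, probe rules, variance models, array weights, a replicate block, fits of only the compared stages and leaving out each array. The arrays of E15.5 replicate 1 and E16.5 replicate 1, and the stage E14.5, were left aside as alternatives chosen after seeing the data. These 2 arrays were those furthest above their stage mean for the cardiomyocyte list.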

Results

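RNA was profiled from the brightest green cells of embryonic mouse heart ventricles. A green fluorescent protein knocked into the Wt1 gene marks cells that express Wt1. Among them are cells of the epicardium, the outer cell layer of the heart, and the arrays do not show that every bright cell was epicardial. Cells were sorted daily between embryonic days 11.5 and 16.5 (E11.5 and E16.5), which gave 6 stages of 3 arrays, 18 arrays in all. Each value is a probe intensity that was already quantile normalized, so every array had a median intensity of 104 and the arrays cannot be ranked by depth. Their number limits the precision. Of the values, 37.6% lay above a background floor of 109 intensity units, and 10950 genes were tested. A level of about 99.0 intensity units, background or an added offset, is still in the values, so that the log2 differences of dim genes are smaller than the differences in RNA. The labels do not say whether arrays of a stage came from separate litters, so p-values measure the spread between these samples, which may be technical. Replicate arrays correlated with Pearson's r of at least 0.990 at E11.5, E12.5 and E14.5, and the lowest values were 0.961 at E13.5, 0.963 at E15.5 and 0.977 at E16.5. No pair of arrays in a stage held identical values. Wt1 itself, the gene behind the sort, was not analysed here, and neither were Mki67 and Tnnt2.

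The first comparison asked how the sorted cells at E16.5 differed from those at E11.5. Endothelial and endocardial genes rose most: 20 of 22 measured markers rose (20 adjusted over the list alone), with a median log2 difference of 2.94. The tight junction gene Cldn5 rose from a mean log2 intensity of 6.71 ± 0.17 (SD, n = 3) at E11.5 to 12.21 ± 0.13 at E16.5 (adjusted p = 3.7e-08). Cd93, a surface receptor of endothelial cells, rose by 5.35 ± 0.27 (SE) on the log2 scale, the adhesion gene Esam by 4.69 ± 0.22 and Icam2 by 4.42 ± 0.31. Cdh5, the cadherin of endothelial junctions, rose by 4.13 ± 0.24, Robo4 rose by 4.25 ± 0.21 on its brightest probe, and its other probes differed by 0.05 on the log2 scale. At E11.5 Cldn5 and Cd93 were above the floor on 2 of 3 arrays and Cdh5 and Robo4 on 1, and the E11.5 means of Cldn5 and Cdh5 lay under it, so that these differences are against values at the background level. Pecam1 was under the floor on all E11.5 arrays and was at least 6.25-fold higher at E16.5. The water channel gene Aqp1 rose by 4.84 ± 0.26 and the caveolar coat gene Cav1 by 4.80 ± 0.24. The retinol-binding gene Rbp7 was at least 17.5-fold higher. Limma's camera called the endothelial list upward (adjusted p = 1.0e-21; adjusted p = 0.069 with an estimated correlation).

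Of 16 Notch pathway genes 7 rose, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.0045; adjusted p = 0.11 with an estimated correlation). The receptor gene Notch4 rose 15.9-fold on its brightest probe and the Notch target Nrarp by 3.33 ± 0.30. In the list of PDGF, IGF and chemokine signals 8 of 27 rose and 5 fell (8 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.35; adjusted p = 6.1e-04 by fry). Its member Pdgfb, a growth factor that recruits mural cells, rose by 4.05 ± 0.35, and Cxcl12, a chemokine, rose 9.53-fold. Among 22 basement membrane genes 12 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.29 with an estimated correlation), led by Col15a1 at 3.45 ± 0.20 and the perlecan gene Hspg2 at 1.74 ± 0.23. Nrarp, Pdgfb and Col15a1 were above the floor on 1 of 3 arrays at E11.5. In the TGF-beta list 7 of 19 rose and 3 fell, also adjusted over the list alone, and camera did not call it (adjusted p = 0.060), while fry called it upward (adjusted p = 2.7e-05). Camera called it upward without E11.5 replicate 1 or 3 (adjusted p = 0.041 and 0.042), with normexp at an offset of 16 (adjusted p = 0.044) and with the arrays of E15.5 replicate 1 and E16.5 replicate 1 left aside (adjusted p = 0.047). The receptor gene Tgfbr2 of this list rose 7.58-fold, on a probe whose companion differed by 0.36 on the log2 scale.

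Of 23 fibroblast markers 13 rose and 2 fell (14 and 3 adjusted over the list alone; adjusted p = 7.7e-05; adjusted p = 0.056 with an estimated correlation). Of 21 interstitial matrix genes 13 rose and 2 fell (13 and 4 adjusted over the list alone; adjusted p = 3.2e-04; adjusted p = 0.063 with an estimated correlation), and 10 genes of each list stand in another list too. The collagen gene Col1a1 rose from 9.95 ± 0.17 to 11.77 ± 0.24 (SD, n = 3), Col14a1 rose 4.02-fold, and the elastin gene Eln rose 6.80-fold. Of 20 genes of epithelial-mesenchymal transition 9 rose and 6 fell (11 and 6 adjusted over the list alone; adjusted p = 0.038; adjusted p = 0.16 with an estimated correlation). Within it the collagen cross-linking gene Lox rose by 1.76 ± 0.22 and the repressor gene Zeb1 by 1.53 ± 0.15, while the fibronectin gene Fn1 fell by 1.63. Snai2, a repressor gene of the same programme, fell by 0.73 (adjusted p = 9.9e-04). Its relative Snai1 rose by 0.39 ± 0.13 (adjusted p = 0.035), a call lost without E16.5 replicate 1, 2 or 3 or E11.5 replicate 2 or 3 (adjusted p = 0.070, 0.10, 0.060, 0.087 and 0.11). The call of the list was lost without E11.5 replicate 2 or E16.5 replicate 2 (adjusted p = 0.056 and 0.052) and with cyclic loess (adjusted p = 0.077).

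Interferon response genes rose in 15 of 21 members and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 1.1e-07; adjusted p = 0.072 with an estimated correlation). Ifitm3, which restricts virus entry, rose 9.37-fold and the guanylate-binding gene Gbp2 rose 5.03-fold. Ifitm1 and the histocompatibility gene H2-D1 rose as well, by 2.21 ± 0.16 and 1.78 ± 0.22, and both belong to families whose members probes may not tell apart. Of 19 dissociation and immediate early genes 12 rose (14 adjusted over the list alone; adjusted p = 1.5e-05; adjusted p = 0.30 with an estimated correlation). Klf2, a transcription factor gene that responds to blood flow, rose 6.65-fold and Atf3, a stress response gene, rose 4.53-fold. The heat shock gene Hspa1a, which has a near-identical copy, rose 7.60-fold. Cell cycle inhibitors rose in 6 of 13 members, also adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.16 with an estimated correlation), with Cdkn1a, the p21 gene, up by 0.93 ± 0.11 and the retinoblastoma gene Rb1 by 0.89 ± 0.12.

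Of 24 S phase genes 13 fell (14 adjusted over the list alone; adjusted p = 7.7e-05; adjusted p = 0.29 with an estimated correlation), among them the chromatin assembly gene Chaf1b by 1.18 and the replication licensing genes Cdt1 and Mcm2 by 0.77 and 0.74 on the log2 scale. Of 24 G2/M genes 6 fell (5 adjusted over the list alone; adjusted p = 0.038; adjusted p = 0.49 with an estimated correlation), and the mitotic kinesin gene Kif2c stood at -0.52 ± 0.08. The G2/M call was lost without E11.5 replicate 1 or 2 or E16.5 replicate 2 or 3 (adjusted p = 0.052, 0.075, 0.0665 and 0.20). All 5 called members of the 7 developmental timing genes fell, also adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.063 with an estimated correlation). Igf2bp1, which encodes a fetal RNA-binding protein, fell by 1.81 and Igf2bp3 fell by 1.56. Of 13 FGF pathway genes 6 fell, also adjusted over the list alone (adjusted p = 0.020; adjusted p = 0.33 with an estimated correlation), with the receptor gene Fgfr2 at -1.68 ± 0.12 and the epicardial ligand gene Fgf9 at -0.48 ± 0.08. The largest falls were those of Prkcb, a protein kinase C gene, at -2.83 ± 0.15, the potassium channel subunit gene Kcne1l at -2.71 ± 0.15, the adhesion gene Flrt3 at -2.38 ± 0.21, the small GTPase gene Rab32 at -2.33 ± 0.16 and Bex2 at -2.28 ± 0.20. Soga3, Ddx25, Prxl2a, Aif1l and Plppr5 fell by 2.20, 2.20, 2.01, 1.96 and 1.93, and Plppr5 was above the floor on 1 of 3 arrays at E16.5. Calb2, the calretinin gene, was at least 3.88-fold lower at E16.5.

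Epicardial and mesothelial identity genes went both ways between these stages. Of 24 members 5 rose and 10 fell (5 and 11 adjusted over the list alone), and neither camera nor fry called the list (median log2 difference -0.22, adjusted p = 0.36 and 0.26). Tcf21, a transcription factor gene of fibroblast progenitors, fell from 11.02 ± 0.27 to 9.55 ± 0.09 (SD, n = 3), Tbx18 fell by 0.94 and the uroplakin gene Upk3b fell by 0.95. The mesothelin gene Msln rose 5.80-fold, Dmkn rose by 2.33 ± 0.29 and the claudin gene Cldn15 by 1.86 ± 0.16. Aldh1a2, which encodes the retinoic acid synthesizing enzyme of the epicardium, differed by -0.33 ± 0.14 (adjusted p = 0.083), and the growth factor gene Igf2 by -0.15 ± 0.07 (adjusted p = 0.096). With the replicate number as a block, which pairs the arrays of these stages, Aldh1a2 was called lower (adjusted p = 0.0375). It was called lower too with array weights, with only these stages fitted and without E13.5 replicate 1 (adjusted p = 0.0080, 0.023 and 0.020), and Igf2 was called lower without E16.5 replicate 1 (adjusted p = 0.046). Bmp4 fell by 1.36 ± 0.19 on its brightest probe, whose companion differed by -0.30.

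Among markers of other cell types the cardiomyocyte list was called upward (median log2 difference 0.87, adjusted p = 0.032; adjusted p = 0.67 with an estimated correlation), but 4 of 24 members rose and 1 fell (3 and 1 adjusted over the list alone). Its mean stood at 10.83 on E15.5 replicate 1 and 10.59 on E16.5 replicate 1, against 8.69 to 9.01 on the other arrays of those stages. With these 2 arrays left aside, a choice made after seeing the data, its median difference was 0.27 (adjusted p = 0.37). The call was also lost without E16.5 replicate 1 or E11.5 replicate 2 alone (adjusted p = 0.52 and 0.073) and with cyclic loess (adjusted p = 0.086), and fry did not call the list (adjusted p = 0.32). The respiratory chain subunit gene Cox6a2, the troponin gene Tnnc1 and the light chain genes Myl3 and Myl2 rose by 2.17, 1.65, 1.41 and 1.26, and Myl7, the atrial light chain gene, fell by 2.15. The Cox6a2, Tnnc1 and Myl3 calls were lost without E16.5 replicate 1 (adjusted p = 0.092, 0.23 and 0.11) and without E11.5 replicate 1 or 2, and that of Tnnc1 on leaving out any of 14 single arrays and with only these stages fitted (adjusted p = 0.062). Without E16.5 replicate 1 the rises of Cox6a2, Tnnc1 and Myl3 were 1.45, 0.96 and 0.90. The Myl2 call was not recomputed with arrays left out. The globin genes Hbb-bs, Hbb-bt and Hba-a1, which are near-identical to other globin genes, rose by 6.09 ± 0.51, 6.07 ± 0.41 and 5.25 ± 0.45, and at E11.5 Hbb-bt and Hba-a1 were above the floor on 2 of 3 arrays. Hbb-b2 was at least 1.48-fold higher at E16.5, the embryonic globin gene Hbb-bh1 was at least 1.36-fold lower, and the embryonic globin genes Hbb-y and Hba-x, above the floor on 1 and 0 of 3 E16.5 arrays, were not called by limma in this contrast. The Hbb-b2 call was lost without any single E11.5 array or E16.5 replicate 1 or 2, and the Hbb-bh1 call without any single E16.5 array, with adjusted p up to 0.14, and both with only these stages fitted (adjusted p = 0.11 and 0.14). Of 8 erythroid markers 4 rose and 1 fell (4 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.21; adjusted p = 0.0068 by fry). Of 9 leukocyte markers 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.27 with an estimated correlation), and Laptm5 was at least 4.71-fold higher. Of 5 neural crest and Schwann markers 4 rose, also adjusted over the list alone (adjusted p = 0.032; adjusted p = 0.13 with an estimated correlation), led by the endothelin receptor gene Ednrb, which rose by 2.53 ± 0.26 on its brightest probe, and the call of the list was lost without E11.5 replicate 2 (adjusted p = 0.056). Of 13 smooth muscle and pericyte markers 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.21 by camera and 7.9e-04 by fry), with the channel subunit gene Abcc9, above the floor on 2 of 3 arrays at E11.5, at 1.61 ± 0.10 and the smoothelin gene Smtn at 0.88 ± 0.18.

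Camera did not call the remaining lists. With E16.5 replicate 1 left out, or the 2 arrays of raised cardiomyocyte markers left aside, it called complement upward (adjusted p = 0.033 and 0.037), and without E16.5 replicate 3 oxidative phosphorylation (adjusted p = 0.016). Fry, which asks only whether genes of a list move one way, called the epithelial junction, Wnt, Hippo-YAP and retinoic acid lists downward (adjusted p = 9.8e-06, 5.2e-04, 0.021 and 0.041) and complement, glycolysis and hypoxia, and apoptosis regulators upward (adjusted p = 8.9e-04, 0.0086 and 0.049). In the order risen then fallen, the members called were 1 and 4 of 16 epithelial junction and polarity genes, 3 and 2 of 11 retinoic acid pathway genes and 4 and 8 of 30 Wnt pathway genes, and these stayed so adjusted over the list alone. Of 20 BMP pathway genes 5 rose and 6 fell (6 and 7 adjusted over the list alone), of 16 Hippo-YAP genes 2 and 5 (4 and 6), of 8 complement genes 5 and 2 (5 and 2), and of 15 imprinted growth genes 1 and 3 (1 and 3). Of 20 glycolysis and hypoxia genes 7 rose and 5 fell (8 and 6 adjusted over the list alone), of 16 apoptosis regulators 5 and 2 (7 and 2), and of 26 cytoskeleton genes 5 and 4 (5 and 4). Of 28 oxidative phosphorylation genes 0 passed limma's test, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. Within these lists the polarity gene Pard6g fell by 1.48, the retinaldehyde dehydrogenase gene Aldh1a1 by 0.84, the BMP-induced gene Id2 by 1.06, the ligand gene Wnt2, above the floor on 2 of 3 arrays at E16.5, by 0.83 and the Hippo effector gene Tead1 by 1.22. The BMP antagonist gene Chrd rose by 1.16 ± 0.14, the complement component gene C2 by 2.64 ± 0.33, the imprinted gene Dlk1 by 1.15 ± 0.08 and Ndrg1, a hypoxia response gene, by 2.28 ± 0.24. The tropomyosin gene Tpm1 fell by 1.41. The 4 sex chromosome genes that were measured are too few for a test as a set, and limma called none of Xist, Eif2s3y, Kdm5d and Uty. The median, mean and test differed in sign for the TGF-beta list, the list of PDGF, IGF and chemokine signals and the cytoskeleton list.

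**Figure D1:**
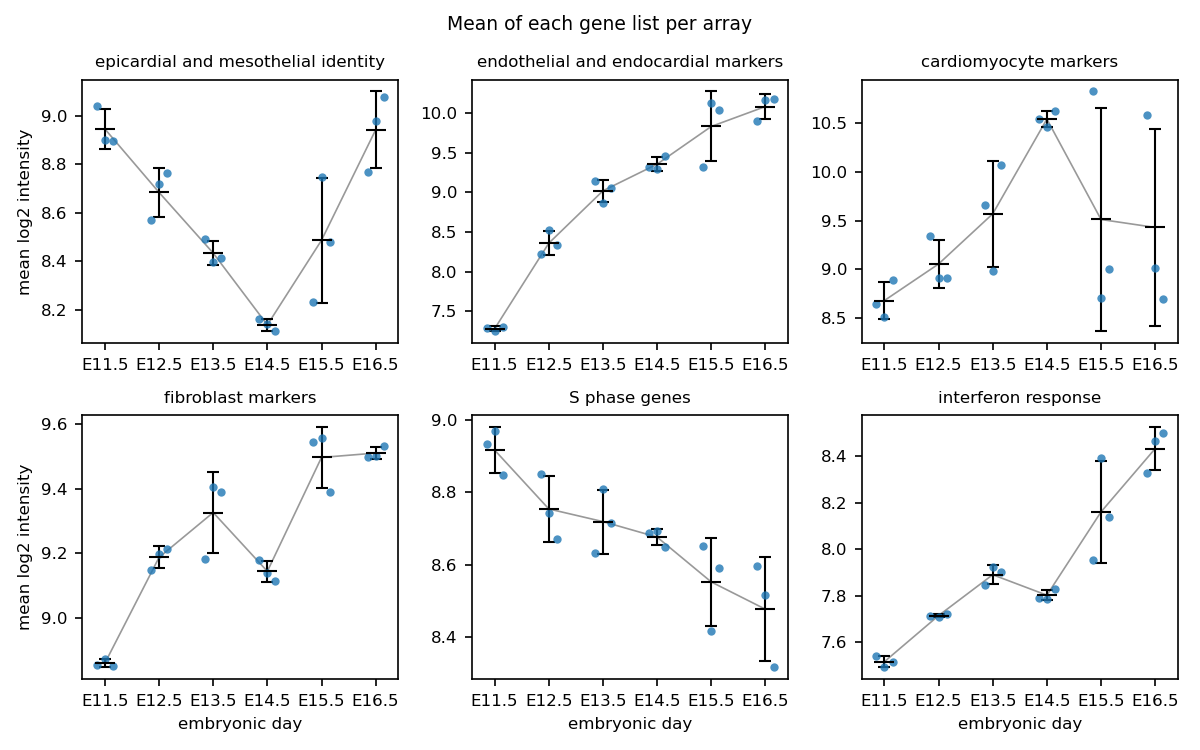
Mean log2 intensity of 6 gene lists (y axis) against embryonic day (x axis), with 1 point per array and bars for the mean ± SD of 3 arrays. Epicardial genes were lowest at E14.5 (8.14 ± 0.02), endothelial genes climbed from 7.28 ± 0.03 to 10.08 ± 0.15, and the cardiomyocyte list spread widely at E15.5 and E16.5.

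In all, limma called 3759 genes between E16.5 and E11.5 at an adjusted p under 0.05, 1728 higher and 2031 lower at E16.5. At least 2-fold differences were seen for 453 of the higher and 131 of the lower genes, and these counts depend on the background step: normexp without control probes, chosen after seeing the data, gave 826 and 337 at an offset of 16 and 581 and 209 at an offset of 50. By camera, 16 of 32 lists were called, 12 upward and 4 downward. With an estimated correlation camera called 0 lists (9 at an unadjusted p under 0.05), and fry called 26. A steady slope per day was called for 4559 genes, 1982 rising and 2577 falling, and any difference between the 6 stages for 4416. With cyclic loess in place of the deposited scaling alone, 2026 genes were higher and 1523 lower at E16.5 than at E11.5, and 2360 slopes rose and 2004 fell.

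**Figure D2:**
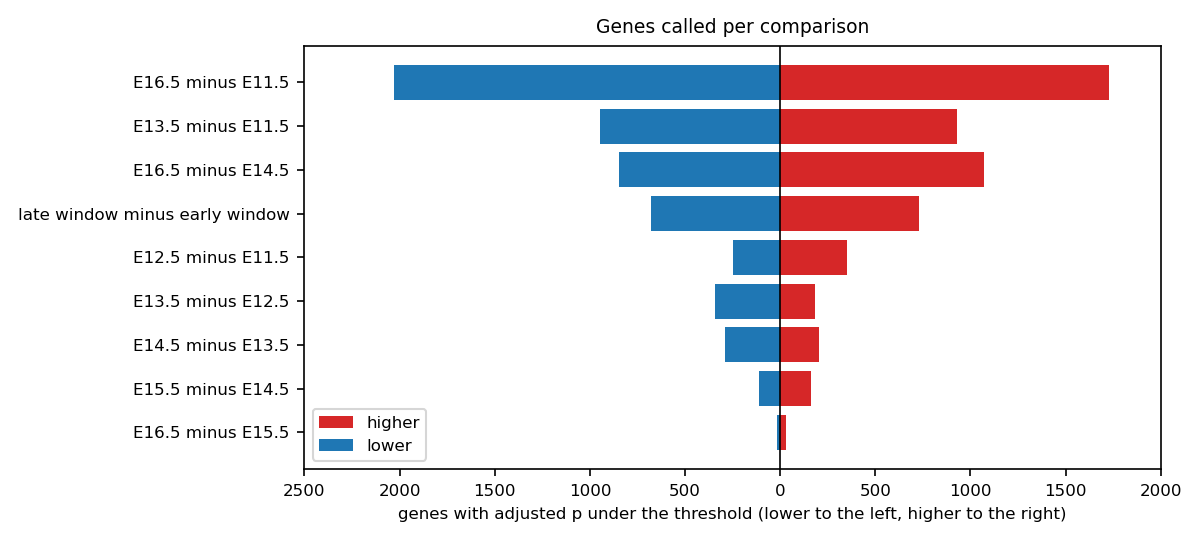
Number of genes called by limma (x axis, genes lower to the left and higher to the right) in each comparison drawn (y axis), which leaves out the slope per day (4559 genes) and the test of any difference between the stages. The bars run from 3759 genes between E16.5 and E11.5 to 48 between E16.5 and E15.5.

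The early window, E13.5 against E11.5, asked which genes moved first. Of 22 endothelial markers 19 rose (20 adjusted over the list alone), with a median of 1.64 (adjusted p = 1.2e-21; adjusted p = 0.047 with an estimated correlation). Cd93 already rose 12.9-fold in this window, and Hbb-bt and Hbb-bs rose by 4.43 ± 0.41 and 4.24 ± 0.51, where Cd93 and Hbb-bt were above the floor on 2 of 3 arrays at E11.5. Epicardial genes fell: 12 of 24 members fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 7.5e-05; adjusted p = 0.14 with an estimated correlation). The keratin genes Krt8 and Krt18 fell by 1.60 and 1.53 on the log2 scale, the uroplakin gene Upk1b by 1.43 and Tbx18 by 0.90, whereas Msln rose by 1.17. The actin-binding gene Aif1l fell by 2.27, Rab32 by 1.84 and Fah, an enzyme of tyrosine breakdown, by 2.08.

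Several other lists were called in the early window. Fibroblast markers rose in 8 of 23 members (8 adjusted over the list alone; adjusted p = 0.0012), smooth muscle markers in 4 of 13 with 1 that fell (7 and 1), interstitial matrix in 10 of 21 with 1 that fell (10 and 1), and Notch genes in 6 of 16 (7). Developmental timing genes fell in 4 of 7 members (4). These lists and the endothelial one were called with an estimated correlation too, the other 5 each at adjusted p = 0.043. Calls that were lost with it covered 7 other lists beside the epicardial one. The upward ones, in the order risen then fallen, were epithelial-mesenchymal transition (7 and 1; adjusted p = 0.064 with an estimated correlation), the TGF-beta pathway (6 and 1; adjusted p = 0.10 with an estimated correlation), glycolysis and hypoxia (7 and 1; adjusted p = 0.10 with an estimated correlation), and interferon response (7 and 1; adjusted p = 0.21 with an estimated correlation). Cardiomyocyte markers (3 and 1) and immediate early genes (1 risen) each had adjusted p = 0.62 with an estimated correlation. S phase genes were called downward, with 5 of 24 fallen (adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone, the counts of these lists in that order were 7 and 2, 7 and 1, 11 and 1, 7 and 1, 3 and 1, 1, and 6.

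The S phase call was lost without E13.5 replicate 1 (adjusted p = 0.12), and the immediate early call without E11.5 replicate 2 or E13.5 replicate 2 or 3 (adjusted p = 0.34, 0.10 and 0.16). Without E11.5 replicate 2 the immediate early median was 0.19 in place of 0.35. That call was lost with cyclic loess too (adjusted p = 0.069). Fry called neither this list nor the cardiomyocyte list in the early window (adjusted p = 0.22 and 0.23). The median, mean and test differed in sign for the retinoic acid and Hippo-YAP lists, neither of which was called by camera or fry.

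In the early window 1874 genes were called by limma, 929 higher and 945 lower at E13.5, and 14 of 32 lists were called by camera, 6 of them with an estimated correlation too. The count was 3247 without E13.5 replicate 1 and 1249 without E13.5 replicate 3.

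The late window, E16.5 against E14.5, has the same length and shares no array with the early one. Epicardial genes rose here: 14 of 24 members rose (16 rose and 2 fell adjusted over the list alone; adjusted p = 2.2e-08; adjusted p = 0.16 with an estimated correlation). Krt8 rose from 7.60 ± 0.05 to 9.72 ± 0.27 (SD, n = 3), Upk1b rose by 1.48 and Upk3b by 0.99, back toward their E11.5 levels of 9.68, 10.69 and 12.69. Tcf21 differed by -0.45 (adjusted p = 0.093). Endothelial markers rose in 17 of 22 members and fell in 1 (20 and 2 adjusted over the list alone; adjusted p = 1.5e-08; adjusted p = 0.25 with an estimated correlation). Nupr1, a stress response gene, rose 7.75-fold and Rbp7 rose 6.42-fold. Wdr92 rose by 2.74 on its brightest probe, and its other probe differed by -0.05. The slow skeletal troponin gene Tnnt1 fell by 2.75, Ccdc3 by 2.22 and the stress-responsive muscle gene Ankrd1 by 2.08 (adjusted p = 0.049). The Ankrd1 call was lost on leaving out any of 12 single arrays, with the highest adjusted p, 0.22, without E16.5 replicate 3.

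Of 13 smooth muscle and pericyte markers 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.035; adjusted p = 0.23 with an estimated correlation), among them the smooth muscle actin gene Acta2 and the desmin gene Des, at -1.38 and -1.27. The cardiomyocyte list had a median of -0.99 (adjusted p = 6.8e-05; adjusted p = 0.53 with an estimated correlation), and 2 of its 24 members, Ankrd1 and Myl4, fell. Adjusted over the list alone 0 passed limma's test, and 12 had an unadjusted p under 0.05. The mean of that list was 10.54 ± 0.08 at E14.5 and 9.43 ± 1.01 at E16.5 (SD, n = 3). At E16.5 it stood at 10.59 on replicate 1 and at 9.01 and 8.69 on replicate 2 and 3. Fry did not call the cardiomyocyte list (adjusted p = 0.11). The mean of the smooth muscle list ranked these arrays alike, at 8.46, 8.24 and 8.14, and was 8.67 ± 0.03 at E14.5. Whether its fall is separate from that of the cardiomyocyte list was not tested. Of the G2/M genes 7 fell (9 adjusted over the list alone; adjusted p = 2.0e-05; adjusted p = 0.25 with an estimated correlation) and of the S phase genes 6 fell (6 adjusted over the list alone; adjusted p = 0.0025; adjusted p = 0.39 with an estimated correlation). Interferon response genes rose in 12 of 21 members (14 and 1 fallen adjusted over the list alone; adjusted p = 1.2e-08; adjusted p = 0.11 with an estimated correlation), and immediate early genes in 8 of 19 (10 adjusted over the list alone; adjusted p = 4.7e-07; adjusted p = 0.25 with an estimated correlation). Fibroblast markers rose in 9 of 23 members and fell in 1 (11 and 3 adjusted over the list alone; adjusted p = 2.9e-04; adjusted p = 0.11 with an estimated correlation), and basement membrane genes rose in 9 of 22 (13 adjusted over the list alone; adjusted p = 1.2e-04; adjusted p = 0.23 with an estimated correlation). Genes named in this paragraph were chosen after their values were seen.

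Smaller lists were called in the late window as well. Leukocyte markers rose in 4 of 9 members (4 adjusted over the list alone; adjusted p = 0.011; adjusted p = 0.25 with an estimated correlation) and complement genes in 5 of 8, with 1 fallen (5 and 1 adjusted over the list alone; adjusted p = 0.011; adjusted p = 0.26 with an estimated correlation). Apoptosis regulators rose in 3 of 16 (3 adjusted over the list alone; adjusted p = 0.035; adjusted p = 0.29 with an estimated correlation), interstitial matrix genes in 5 of 21 with 1 fallen (8 and 3 adjusted over the list alone; adjusted p = 0.046; adjusted p = 0.25 with an estimated correlation), and neural crest markers in 3 of 5 (3 and 1 fallen adjusted over the list alone; adjusted p = 0.0499; adjusted p = 0.23 with an estimated correlation). The oxidative phosphorylation list had a median of -0.26 (adjusted p = 0.0084; adjusted p = 0.65 with an estimated correlation), with 0 members called by limma, also adjusted over the list alone, and 6 at an unadjusted p under 0.05. Its call was lost without E16.5 replicate 3 (adjusted p = 0.16). Its mean on E16.5 replicate 1, 2 and 3 was 10.50, 9.99 and 9.88, which ranks these arrays as the cardiomyocyte list did. Whether its fall is separate from that of the cardiomyocyte list was not tested. The smooth muscle call was lost without E14.5 replicate 3 (adjusted p = 0.055). That of the apoptosis list was lost without E14.5 replicate 3 or E16.5 replicate 3 (adjusted p = 0.070 and 0.0503). The interstitial matrix call was lost without E11.5 replicate 1, E14.5 replicate 2 or 3, E15.5 replicate 1 or 2 or E16.5 replicate 1 or 3, with adjusted p up to 0.070. The neural crest call was lost on leaving out any of 13 single arrays, with adjusted p up to 0.11. With cyclic loess the interstitial matrix and neural crest calls were both lost (adjusted p = 0.052 and 0.065). The interstitial matrix call was lost with normexp at an offset of 16 (adjusted p = 0.0575), and the neural crest call with an added offset of 16 and no normexp (adjusted p = 0.0504). With the 2 arrays of raised cardiomyocyte markers left aside, the interstitial matrix and neural crest calls ended too (adjusted p = 0.086 and 0.11). These 2 arrays stood out within their own stages. The E14.5 arrays, with means of 10.46 to 10.63 for the cardiomyocyte list, were kept. This setting therefore does not even out cardiomyocyte markers between E14.5 and E16.5.

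In the late window 1915 genes were called by limma, 1069 higher and 846 lower at E16.5, and 16 of 32 lists by camera. With an estimated correlation camera called 0 lists (6 at an unadjusted p under 0.05), and fry called 18. The median, mean and test differed in sign in this window for the epithelial junction, epithelial-mesenchymal transition, retinoic acid, TGF-beta, Hippo-YAP, PDGF, IGF and chemokine, imprinted and cytoskeleton lists, which neither camera nor fry called. Cyclic loess gave 1217 genes higher and 601 lower. The count of genes was 1232, 1081 and 1224 without E14.5 replicate 1, 2 and 3, and 1193 and 1052 without E16.5 replicate 2 and 3.

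**Figure D3:**
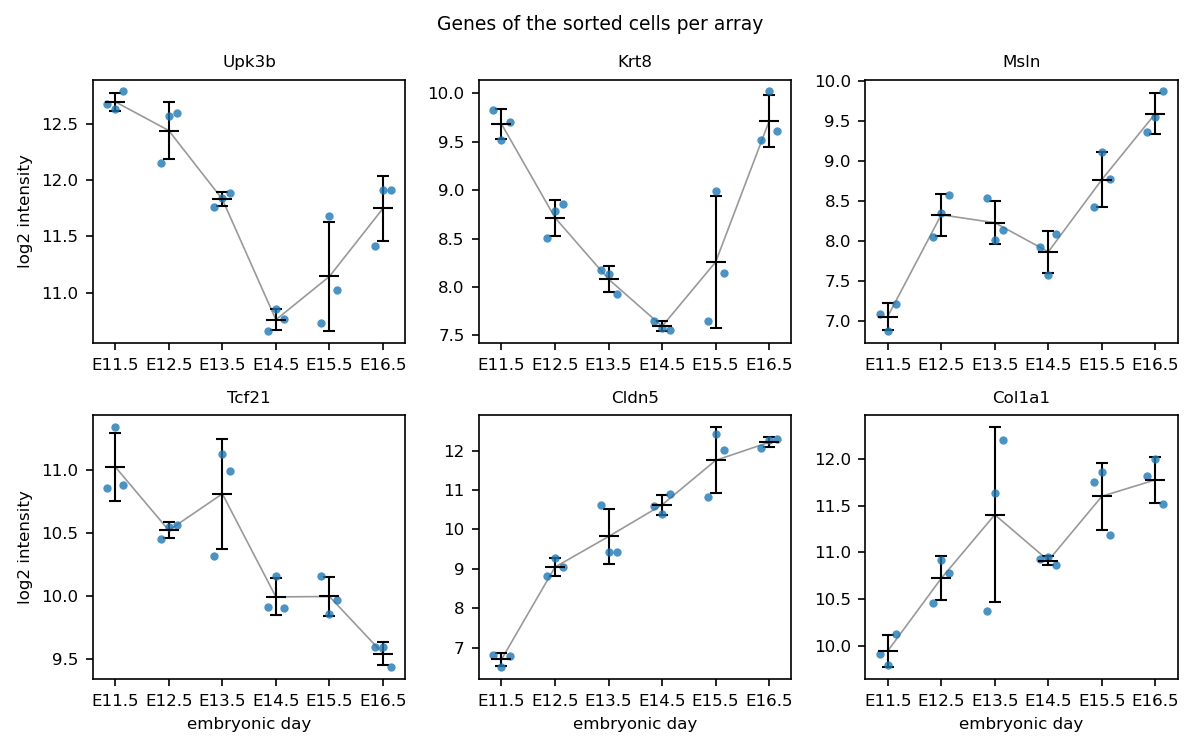
Log2 intensity (y axis) of Upk3b, Krt8, Msln, Tcf21, Cldn5 and Col1a1 against embryonic day (x axis), with 1 point per array and bars for the mean ± SD of 3 arrays. Krt8 was lowest at E14.5 with a mean of 7.60, while Cldn5 rose from 6.71 to 12.21.

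The difference between the windows, late minus early, tested whether genes moved differently at the start and at the end. Epicardial genes were higher in this difference: 15 of 24 members passed, all of them upward (17 adjusted over the list alone), with a median of 1.17 (adjusted p = 5.1e-12; adjusted p = 0.071 with an estimated correlation). Krt8 differed by 3.72 ± 0.34, Krt18 by 3.13 ± 0.29 and Upk1b by 2.91 ± 0.29, and the prostaglandin-degrading enzyme gene Hpgd by 3.06 ± 0.28, each having fallen in the early window and risen in the late one. The matrix gene Tgfbi, which rose by 2.98 early and fell by 1.25 late, differed by -4.23 ± 0.19. Ccdc3 differed by -3.50 ± 0.29, Tnnt1 by -4.87 ± 0.72 and the myoglobin gene Mb by -3.88 ± 0.96. The cardiomyocyte list had a median of -2.29 with 7 of 24 members lower (17 adjusted over the list alone; adjusted p = 5.9e-07; adjusted p = 0.41 with an estimated correlation). Endothelial markers, which rose in both windows, rose less in the late one, with 12 of 22 lower and 1 higher in the difference (14 and 2 adjusted over the list alone; adjusted p = 1.6e-07; adjusted p = 0.32 with an estimated correlation). Of 13 smooth muscle markers 7 were lower (7 adjusted over the list alone; adjusted p = 2.5e-04; adjusted p = 0.058 with an estimated correlation).

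Other lists were called in the difference with smaller medians. Glycolysis and hypoxia genes were lower in 9 of 20 members and higher in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.0016; adjusted p = 0.27 with an estimated correlation), G2/M genes lower in 6 of 24 (7 adjusted over the list alone; adjusted p = 0.0038; adjusted p = 0.41 with an estimated correlation), and TGF-beta genes lower in 4 of 19 (4 adjusted over the list alone; adjusted p = 0.0062; adjusted p = 0.27 with an estimated correlation). Notch genes were lower in 3 of 16 members (4 adjusted over the list alone; adjusted p = 0.0038; adjusted p = 0.20 with an estimated correlation). Of the oxidative phosphorylation genes 1 of 28, Atp5o, was lower, and 0 were by limma adjusted over the list alone, with 8 at an unadjusted p under 0.05 (adjusted p = 0.0017; adjusted p = 0.57 with an estimated correlation). Complement genes were higher in 3 of 8 and lower in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.044; adjusted p = 0.38 with an estimated correlation), and immediate early genes higher in 3 of 19 (4 adjusted over the list alone; adjusted p = 0.018; adjusted p = 0.57 with an estimated correlation). With a replicate block the complement call was lost (adjusted p = 0.055).

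The difference was called for 1410 genes by limma, 731 higher and 679 lower, and the count was 2403 without E13.5 replicate 1. With the mean of the cardiomyocyte list as a covariate the count was 820. Of the genes called in both windows 262 rose in both, against 90.7 for independent lists, and 140 fell in both, against 73.0. Another 117 rose early and fell late, against 71.8, and 96 fell early and rose late, against 92.3. Across genes, which are not independent replicates, the changes of the windows had a Pearson's r of 0.13 and a Spearman's rho of 0.15. The median, mean and test differed in sign in this difference for the fibroblast, leukocyte, neural crest, cell cycle inhibitor and Hippo-YAP lists, which neither camera nor fry called.

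Neighbouring days were compared in 5 steps. From E11.5 to E12.5 the matrix gene Thbs2 rose 7.65-fold, Cd93 rose 6.75-fold and Hspa1a rose 6.65-fold, with Cd93 above the floor on 2 of 3 arrays at E11.5, while Aif1l fell by 1.73, Tmem255a fell by 1.89 and the mitochondrial gene Mgarp fell by 1.32. Limma called 599 genes in this step, 353 higher and 246 lower. The count was 900 without E13.5 replicate 1, 355 without E11.5 replicate 2, and 393 and 379 without E12.5 replicate 2 and 3.

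From E12.5 to E13.5 Col15a1 rose 2.66-fold, and Socs3, an inhibitor of cytokine signals, fell by 1.56. Hbb-bt rose 3.90-fold, the endothelial transcription factor gene Sox7 rose 2.65-fold, and Hspa1a and Thsd4 fell by 2.05 and 1.36. The Hbb-bt call was lost without E12.5 replicate 1, 2 or 3 or E13.5 replicate 3, that of Sox7 without E12.5 replicate 3 or E13.5 replicate 3, that of Hspa1a without E12.5 replicate 2 or 3 or E13.5 replicate 3, and that of Thsd4 without E12.5 replicate 2, with adjusted p up to 0.10. With only these stages fitted all 6 calls were lost (Col15a1 adjusted p = 0.082, Socs3 0.058), and 0 genes were called in this step. Limma called 526 genes, 181 higher and 345 lower at E13.5. The count was 2593 without E13.5 replicate 1, 127 and 112 without E13.5 replicate 2 and 3, and 93 and 92 without E12.5 replicate 2 and 3. It was 851 with the 2 arrays of raised cardiomyocyte markers left aside and 288 with the 3 arrays of E14.5 left aside.

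From E13.5 to E14.5 the vascular amine oxidase gene Aoc3 rose 2.97-fold. The gap junction gene Gja5 rose 2.30-fold, Gm5801 rose 2.51-fold on its brightest probe, and Upk3b and the fibulin gene Fbln2 fell by 1.07 and 1.23. These last 4 calls were each lost without E13.5 replicate 2, E14.5 replicate 1 or E14.5 replicate 3, and that of Gm5801 also without E14.5 replicate 2, with adjusted p up to 0.12. With only these stages fitted the Gja5, Gm5801 and Fbln2 calls were lost (adjusted p = 0.065, 0.18 and 0.083). The log2 difference of Gm5801 was 1.33 on its brightest probe. It was 0.47 with the mean of all its kept probes, where the call was lost (adjusted p = 0.094), and 0.80 without E13.5 replicate 2. Limma called 497 genes, 205 higher and 292 lower at E14.5. The count was 2375, 37 and 187 without E13.5 replicate 1, 2 and 3, it was 78, 142 and 60 without E14.5 replicate 1, 2 and 3, and 864 without E15.5 replicate 1. With E15.5 replicate 1 and E16.5 replicate 1 left aside, and the E14.5 arrays of similarly high cardiomyocyte markers kept, it was 1061.

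From E14.5 to E15.5 Nupr1 rose 3.85-fold and Klf2 rose 2.92-fold. C2 rose 2.86-fold, and Ccdc3, Tnnt1 and the troponin gene Tnni2 fell by 1.29, 2.14 and 1.46. The Ccdc3 call was lost without E14.5 replicate 2 (adjusted p = 0.055), the C2 and Tnni2 calls without E14.5 replicate 1, 2 or 3 or E15.5 replicate 2 or 3, and the Tnnt1 call on leaving out any of 12 single arrays, with adjusted p up to 0.21. With only these stages fitted all 6 calls were lost (Nupr1 adjusted p = 0.076, Klf2 0.077). Limma called 275 genes, 162 higher and 113 lower at E15.5. The count was 1312, 42 and 62 without E15.5 replicate 1, 2 and 3, and 59, 17 and 110 without E14.5 replicate 1, 2 and 3. It was 174 without E11.5 replicate 1, 181 and 171 without E12.5 replicate 2 and 3, and 538 without E13.5 replicate 1. With E15.5 replicate 1 and E16.5 replicate 1 left aside, and the E14.5 arrays of similarly high cardiomyocyte markers kept, it was 1516.

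From E15.5 to E16.5 Dmkn rose 3.04-fold, Krt8 rose 2.74-fold and the galectin gene Lgals7 rose 2.64-fold. These calls were lost without E15.5 replicate 1 or 3 or E16.5 replicate 2 or 3, and that of Dmkn also without E11.5 replicate 2 or E12.5 replicate 3, with adjusted p up to 0.17. With only these stages fitted all 3 were lost (adjusted p = 0.70). With the 3 arrays of E14.5 left aside the Dmkn, Krt8 and Lgals7 calls were lost too (adjusted p = 0.084, 0.057 and 0.071). Limma called 48 genes, 33 higher and 15 lower at E16.5. The count was 12, 201 and 6 without E15.5 replicate 1, 2 and 3, and 134, 10 and 12 without E16.5 replicate 1, 2 and 3. It was 29 and 25 without E11.5 replicate 1 and 2, 26 without E12.5 replicate 3, and 29 and 28 without E14.5 replicate 1 and 2. With the 3 arrays of E14.5 left aside it was 10.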

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

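The regroupings of arrays and the test with cardiomyocyte RNA as a covariate were planned before their results were seen, and the tests of a lower share of the main cell type, of a fixed endothelial profile, of dilution by one factor and of red blood cell RNA, and the estimated correlation in the fit with that covariate, were chosen after the result was seen.

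The changes of 1410 genes differed between the late and the early window by the test of that difference itself. With the mean of the cardiomyocyte list as a covariate 820 genes were called. The largest positive differences were those of Krt8 (3.72), Krt18 (3.13), Hpgd (3.06) and Upk1b (2.91) on the log2 scale, and the largest negative ones those of Tnnt1 (-4.87), Tgfbi (-4.23), Mb (-3.88) and Ccdc3 (-3.50). Among gene lists the median difference was 1.17 for epicardial and mesothelial identity, 0.40 for immediate early genes and 0.33 for complement. It was -2.29 for cardiomyocyte, -1.04 for endothelial and -0.46 for smooth muscle markers, -0.50 for glycolysis and hypoxia, -0.43 for oxidative phosphorylation, -0.32 for the Notch and -0.17 for the TGF-beta pathway, and -0.19 for G2/M genes. With an estimated correlation none of these lists was called by camera, and the smallest adjusted p was 0.058, with 5 at an unadjusted p under 0.05. Whether the smooth muscle and oxidative phosphorylation differences are separate from that of the cardiomyocyte list was not tested. Of 100 regroupings of the arrays 2, the real one included, gave as many genes, and the other gave 1660. The regroupings shuffled arrays freely over the stages of the 2 windows. They ask whether these stages differ at all, and cannot decide whether the late and early changes are equal.

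Endothelial markers were higher at E16.5 than at E11.5 by a median of 2.94. A lower share of the main cell type would raise the markers of other types alike, but the endothelial median exceeded the next highest, that of the cardiomyocyte list, by 2.08. A permutation test that reassigned genes between the lists gave p = 1e-04 with 10000 draws, the smallest these can give. Genes of a list vary together, with an estimated correlation of 0.54 for endothelial and 0.89 for cardiomyocyte genes. This p therefore does not measure the spread between samples. A growing share of endothelial cells of one fixed profile would raise the members by one factor only if no other sorted cell expressed them. Their background-subtracted changes from E12.5 to E16.5 had an SD of 1.28 against a root mean square standard error of 0.24. They ran from 0.11 for Npr3 to 5.26 for Gpihbp1. The list joins endothelial and endocardial genes, and their expression in other sorted cells was not measured. This spread therefore cannot decide on a growing share. The leukocyte list had a mean of 6.76 at E11.5, at the floor, and the neural crest list held 5 genes, so these lists say little. The cardiomyocyte and smooth muscle lists started at 8.68 and 7.99, above the endothelial 7.28, and rose by medians of 0.87 and 0.29. If their members mark other cell types alone, which was not measured, a lower share of the main cell type alone does not explain the whole rise. A growing share of endothelial cells, of a fixed profile or maturing, may account for it. A gate on Wt1-GFP bright cells would be expected to remove cells that are not bright, but whether endothelial cells were bright was not measured here. A change of the sorted cells themselves with age may account for the rise as well. These explanations were not told apart.

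Epicardial markers fell in the early and rose in the late window. With the mean of the cardiomyocyte list as a covariate the median difference between the windows was 1.07 in place of 1.17, and 10 in place of 15 of 24 members were called. Camera's adjusted p was 9.4e-11 with it (adjusted p = 0.027 with an estimated correlation, against 0.071 without the covariate). The mean of the list over the arrays differed by 0.99 ± 0.12 (SE) in place of 1.32 ± 0.16. A straight-line effect of the cardiomyocyte list mean therefore does not account for the whole difference. Of the cardiomyocyte members themselves 5 were called in this difference with the covariate, against 7 without it. The covariate may thus not remove all cardiomyocyte RNA, and the fit cannot exclude such RNA as the cause. The members' background-subtracted changes from E11.5 to E14.5 had an SD of 1.21 against a root mean square standard error of 0.26, from -2.94 for Krt8 to 2.04 for Msln. Dilution by one factor, with no other change, therefore does not describe all members. Dilution together with changes of single genes cannot be excluded by this spread. The mean of the cardiomyocyte list was highest at E14.5 (10.54 ± 0.08, SD, n = 3). A change of the epicardium with embryonic age, which the design names, may account for the pattern and stays untested.

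The globin genes Hbb-bs, Hbb-bt and Hba-a1 rose by 6.09, 6.07 and 5.25 on the log2 scale between E11.5 and E16.5 and Hbb-b2 was at least 1.48-fold higher, while Hbb-bh1 was at least 1.36-fold lower and Hbb-y and Hba-x, above the floor on 1 and 0 of 3 E16.5 arrays, were not called by limma in this contrast. Of 3 erythroid markers that are not globins 2 were called upward, Alas2 and Slc4a1, both under the floor on all E11.5 arrays and Slc4a1 at least 1.43-fold higher at E16.5, and the third, Hemgn, was not called. Red blood cell RNA in the sorted samples would give such rises. A gate on Wt1-GFP bright cells would be expected to remove such cells, but the purity of the sort was not measured here. These erythroid genes lie near the floor, and free RNA was not tested. Probes that cannot tell near-identical globin genes apart stay open, and no biological explanation was tested.

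Other groupings of the arrays were counted for each comparison. For any change between the stages 1 of 100 regroupings, the real one, gave as many genes as the 4416 called (highest other 7), and for the slope per day 1 of 100 did so (4559 against 721). If arrays vary independently of each other, chance alone, with no difference between the stages, is thus excluded for both. The labels do not say whether arrays of a stage came from separate litters. If they did not, a chance difference between litters could give such counts, and these regroupings cannot exclude it. For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real count and the highest other were 3759 and 0 for E16.5 against E11.5, 1874 and 7 for the early window, 1915 and 0 for the late window, 599 and 0 for E12.5 against E11.5, 497 and 235 for E14.5 against E13.5, and 275 and 0 for E15.5 against E14.5, with 1 split as large in each. For E13.5 against E12.5 the real count was 526 and 2 splits were as large, the other calling 576 with E12.5 replicate 1 beside E13.5 replicate 2 and 3. For E16.5 against E15.5 it was 48, and 2 splits were as large. The other called 288, with E15.5 replicate 1 and 3 beside E16.5 replicate 1, which points to a structure of the samples that the stages do not give. Among the 4 splits of that step that part all 3 same-number pairs the highest other was 0.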

How the results depend on the processing

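The settings named below as leaving arrays aside, normexp without control probes, the floors and cyclic loess on the deposited values were chosen after seeing the data. Of 2633 values of named genes under settings other than leaving out an array, 2577 kept direction and side of the threshold, 51 lost and 4 gained a call, and 1 reversed: Wdr92 in the late window stood at -0.046 with only probes above the floor on all 18 arrays, where another probe was used. Leaving out single arrays lost 128 and gained 2 calls among 3474 values of named genes, and lost 37 and gained 10 among 1728 values of lists, called or not, with 0 reversed. Of 832 list values under other settings 55 lost and 30 gained a call.

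Array weights gave 7562 genes with any change, 4130 in the early window, 3755 in the late window, 3395 for the difference between the windows and 1580, 3620, 3708, 2971 and 653 in the 5 steps. Testing every kept probe, which adds tests, gave 5889 for E16.5 against E11.5 and 7376 for the slope. Fitting only the compared stages, which leaves fewer degrees of freedom, gave 1074 in the early window and 1109, 0, 25, 12 and 0 in the steps, where limma's unadjusted p was under 0.05 for 1698 and 687 genes at the zeros. Without the floor filter E14.5 against E13.5 and E15.5 against E14.5 had 320 and 177 genes, and with probes above the floor on all 18 arrays E15.5 against E14.5 and E16.5 against E15.5 had 157 and 15. With the arrays of E15.5 replicate 1 and E16.5 replicate 1 left aside the steps from E12.5, E13.5 and E14.5 had 851, 1061 and 1516. The E14.5 arrays, with similarly high cardiomyocyte markers, were kept in these fits. With E14.5 left aside the steps from E12.5 and E15.5 had 288 and 10. With an estimated correlation 0, 6 and 0 lists were called (16, 14 and 16 with the preset one; 9, 11 and 6 at an unadjusted p under 0.05), and fry called 26 for E16.5 against E11.5. Except where stated, the cause was not tested.

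Leaving out single arrays gave 3802 to 5929 genes with any change, 3148 to 4326 for E16.5 against E11.5, 4075 to 5103 for the slope, 1249 to 3247 in the early window, 1052 to 2516 in the late window, and 1057 to 2403 for their difference. The highest of these was without E13.5 replicate 1 in each case. In the steps the ranges were 355 to 900, 92 to 2593, 37 to 2375, 17 to 1312 and 6 to 201. Lists called ranged from 12 to 17, 13 to 15 and 12 to 16.

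A replicate block, fitted over all 18 arrays, gave 4128 genes for E16.5 against E11.5, 720 for E12.5 against E11.5 and 70 for E16.5 against E15.5. In these pairs of stages every same-number correlation was over 0.1. It changed no list call for E16.5 against E11.5, and of the calls of named genes that of Aldh1a2 alone, which it gained (adjusted p = 0.0375). Lists were not tested in the steps. In the other pairs of stages that were compared not every same-number correlation was over 0.1. Over all 15 pairs of stages 32 of 45 same-number correlations were over 0.1, from -0.25 to 0.73, and 15 of 18 arrays correlated best with their own number. The highest joined E15.5 replicate 1 and E16.5 replicate 1, the arrays of raised cardiomyocyte markers. All 3 were over 0.1 for 5 pairs of stages, E12.5 with E14.5 and E12.5 with E16.5 among them, which were not compared. The block gave 804 for E14.5 against E13.5 and 453 for E15.5 against E14.5, and the complement call in the difference between the windows was lost (adjusted p = 0.055). Signals near the background limit what can be seen of dim genes. Scaling to the 75th percentile (the arrays share 1 distribution), a slide block, background correction with control probes and filters on detection p were not run.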

Other observations

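The checks below were chosen after the values were seen.

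The glycolysis and hypoxia list, which camera did not call between E11.5 and E16.5, had 7 members that rose and 5 that fell. Ndrg1, Egln3, Ankrd37, Car9, Aldoc, Pdk1 and Hk1 rose by 2.28, 1.61, 1.36, 1.15, 0.55, 0.46 and 0.29 on the log2 scale, and Slc2a1, Slc2a3, Tpi1, Pgam1 and Slc16a3 fell by 0.53, 0.50, 0.44, 0.38 and 0.21. At E11.5 Car9 and Hk1 were above the floor on 2 of 3 arrays. In the list of PDGF, IGF and chemokine signals, which camera did not call either, Igfbp7, Igfbp3 and Igfbp4 rose by 2.79, 1.90 and 1.42, Igfbp6 was at least 5.41-fold higher at E16.5, Igfbp5 and Igfbp2 stood at 0.05 and -0.10 and were not called by limma, and the heparin-binding growth factor genes Mdk and Ptn fell by 1.32 and 1.30. No group within these lists was tested.

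The arrays of E13.5 differed among themselves. On the third principal component E13.5 replicate 2 and 3 lay at -24.2 and -23.0, E13.5 replicate 1 at 10.5 and the other 15 arrays between -1.63 and 6.92, so that on it replicate 2 and 3 lay far from all other arrays and replicate 1 nearer to them. Array weights gave E13.5 replicate 1 a weight of 0.16. The mean of the immediate early list was 8.75 on it and 9.48 and 9.49 on the others, and that of the cardiomyocyte list was 9.66 against 8.99 and 10.07. Gstp1, Rps6, Zfp36, Tmsb10 and Vim were lower on it, at -2.51, -2.38, -2.32, -2.24 and -1.75 relative to the mean of the others, and Rps3a1 and Srr were higher, at 2.09 and 2.01. Rps6 stood at 10.28 on it, 12.75 and 12.57 on the others and at means of 11.10 to 11.81 in the other stages. Placed in time by genes with a slope in the arrays of other replicate numbers, it came at day 13.6 and E12.5 replicate 1 at day 12.5, in the order of their labels, while E15.5 replicate 1 came at day 14.7 and E16.5 replicate 1 at day 15.8. Others came late, E13.5 replicate 3 at day 13.99 and E15.5 replicate 2 at day 16.04, after E16.5 replicate 1. On the second component E15.5 replicate 1 lay at -16.6, among the E14.5 arrays at -17.2 to -15.4, and E15.5 replicate 2 and 3 at 13.9 and 6.29. Its endothelial mean was 9.32, near the 9.35 of E14.5, against 10.13 and 10.03 on replicate 2 and 3. Its fibroblast mean, 9.54, was nearer to their 9.56 and 9.39 than to the 9.14 of E14.5.

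Xist, which marks the inactive X chromosome of female cells, had stage means of 9.18, 9.71, 8.48, 10.62, 7.86 and 10.19 from E11.5 to E16.5, with an SD of up to 1.55 within a stage. The Y-linked genes Eif2s3y, Kdm5d and Uty were not called between E16.5 and E11.5.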
